A study of Homo sapiens with 6 samples.

How the data were processed

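RNA-seq was performed on 6 libraries labelled CAPAN-2, an established human pancreatic ductal adenocarcinoma cell line. Per the labels, 3 libraries came from control cells and 3 from cells with SIRT4 overexpression. Total RNA was extracted with TRIzol, and libraries were built with an NEBNext Ultra kit, per the labels' protocols. STAR, featureCounts, Subread and DESeq2 and the genome build hg38 are named in the submitters' processing notes, without versions, settings or roles. The vector, the duration of overexpression, the culture conditions, the annotation release and the strand setting are not given in the sources used here.

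The deposited table held 67140 Ensembl gene identifiers for the 6 libraries as whole numbers, which were treated as estimated counts. The low values of the deposited estimated counts did not fall steadily from 1: in control replicate 1, 1069 genes stood at 1, 1020 at 2, 792 at 3, 1278 at 4, 905 at 5, 443 at 6, 387 at 7 and 674 at 8. The rises at 4 and 8 would be unusual in a plain tally of fragments. Whether several units stand for 1 fragment was not measured. How the deposited estimated counts were derived is not given in the sources used here. The values were already whole, so rounding changed nothing, and a recalculation with every value divided by 4 was made after seeing the data. Totals ran from 50945991 to 65156041 units per library. The quasi-likelihood dispersion was estimated from the spread between libraries, so it does not take these units for independent reads. The low-count filter and the count model still used the units as counts.

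Gene symbols came from a table of Ensembl identifiers that matched 60357 of the 67140 identifiers, and from GENCODE release 29 for 296 others. Coordinates are those of GENCODE release 29 on GRCh38, the assembly that hg38 denotes, counted from 1. Of 920 memberships in 39 gene lists, 918 were matched to the table.

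Levels as CPM, counts scaled to the library size, were computed from the deposited estimated counts with TMM-scaled library sizes. After filterByExpr, 20786 genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM, robust glmQLFit, glmQLFTest) on all 6 libraries, without covariates, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Gene lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether a list changed at all and makes no comparison with other genes, was also run. SIRT4 was left out of the lists in these tests. Values of single measures were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

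The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took SIRT4, then the 10 genes higher and the 10 lower with the largest log2 fold change among genes past the threshold with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups. It also took up to 3 members of each list with the smallest adjusted p, the sirtuins, and GLUD1, PDHA1, DLAT, MLYCD and SLC25A5 whether or not they passed. Alternatives were DESeq2 size factors, library size only, removal of the SIRT4 row, no filter and a stricter filter (10 counts in 3 libraries and a mean of 1 CPM), the DESeq2 1.42.0 Wald test, limma-voom, glmTreat against a fold change of 1.2, the replicate number as a block, and leaving out each library in turn. After the data were seen, division by 4, removal of read-through loci, and offsets for transcript GC content and length were added.

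The procedure was tested on simulated data for the comparison of SIRT4 with control, with 200 changed genes among 20086. These 200 were drawn from the more abundant genes only, so the recovery of scarcer genes was not measured. The procedure recovered 37.3% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 93.9% of those changed 4-fold. Of the genes called there, 14.9% had not been changed, more than the threshold of 0.05 aims for. When none had been changed, 4 genes were called. In the real comparison 17.1% of tested genes were called, a larger share than was changed in the simulation. That share affects which genes pass the Benjamini-Hochberg adjustment, so these rates cannot be carried over to the real calls. No library was left out.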

Results

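Gene expression was measured in 3 libraries labelled control and 3 labelled SIRT4 overexpression, from cells labelled CAPAN-2. SIRT4 is a mitochondrial sirtuin with reported activity on glutamate dehydrogenase, the pyruvate dehydrogenase complex and malonyl-CoA decarboxylase. Total estimated counts were 57626801, 50945991 and 57598860 in control replicates 1 to 3, and 65156041, 51999089 and 59265078 in SIRT4 replicates 1 to 3. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Principal component 1 held 32.6% of the variance and separated the groups. Pearson correlations of log2 CPM, across genes, were 0.972 to 0.975 within groups and 0.963 to 0.969 between them.

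The series asks which genes change when SIRT4 is overexpressed in this line. SIRT4 itself (ENSG00000089163, GRCh38 chromosome 12, 120302316 to 120313249, plus strand) was at 2.08 ± 0.34 CPM in control (SD, n = 3) and 3.23 ± 0.41 CPM in SIRT4 libraries (SD, n = 3). Its estimated counts were 144, 101 and 106 in control and 215, 144 and 208 in SIRT4 libraries, so the 3 SIRT4 values were at or above every control value before scaling and all above them in CPM. The log2 fold change was 0.63 (SE 0.21), with an adjusted p of 0.0752 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which is not past the threshold. DESeq2 gave a log2 fold change of 0.64 and an adjusted p of 0.0385, and the 17 alternatives gave adjusted p-values from 0.0385 to 0.248.

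**Figure D1:**
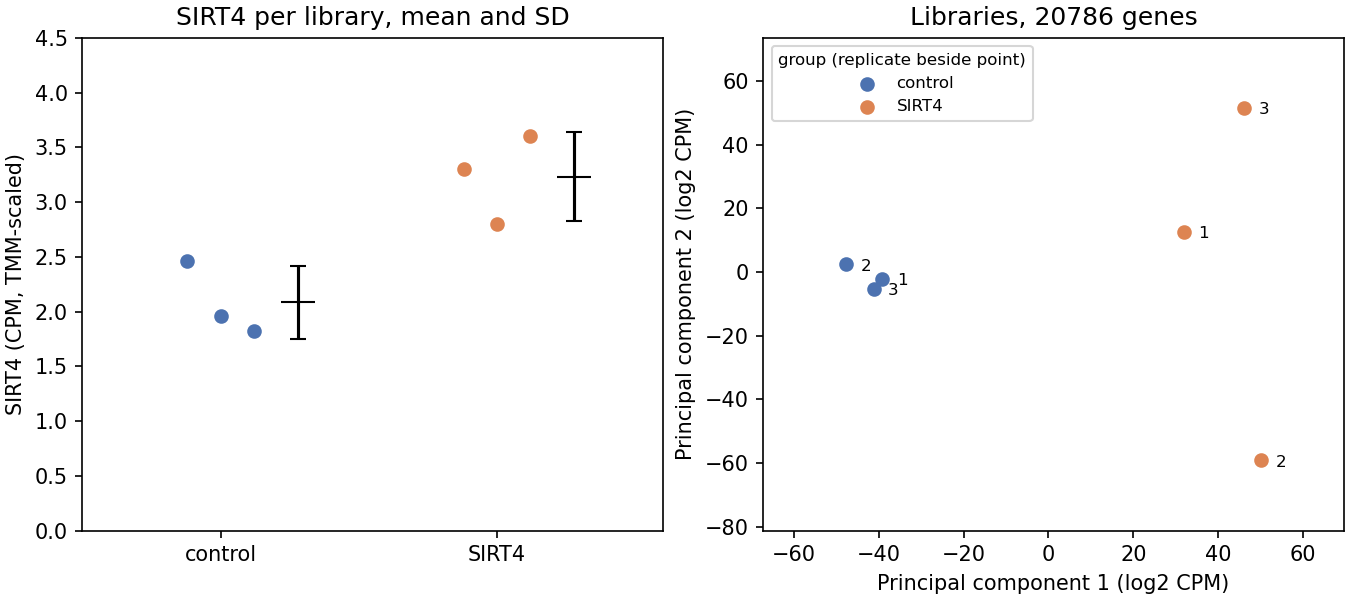
Left, SIRT4 in CPM (TMM-scaled) in each of 3 control and 3 SIRT4 libraries, with the mean and SD of each group beside the points; the means were 2.08 and 3.23 CPM. Right, the same libraries on principal components 1 and 2 of log2 CPM, where every control library lies below 0 and every SIRT4 library above 0 on component 1.

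Of the other sirtuins, SIRT1, a nuclear deacetylase, was lower (log2 fold change -0.35, SE 0.06, adjusted p = 0.00479 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while SIRT2, SIRT3, SIRT5, SIRT6 and SIRT7 did not pass, with log2 fold changes from -0.22 to 0.02. Among enzymes and partners linked to SIRT4, DLAT, the E2 subunit of pyruvate dehydrogenase, rose by 0.61 on the log2 scale, and the ADP/ATP carrier SLC25A5 rose by 0.21. GLUD1 (0.09), PDHA1 (0.13) and MLYCD (0.04) did not pass.

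Across the transcriptome, 1950 genes were higher and 1595 lower in SIRT4 libraries among 20786 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 3545 changed genes, 387 changed at least 2-fold, 154 higher and 233 lower. The groups did not overlap for any of the changed genes, nor for 37.6% of all tested genes, where chance gives 10%. The count of lower genes was 978 without control replicate 3, 1021 without SIRT4 replicate 2 and 1058 without SIRT4 replicate 3. The median log2 fold change of all tested genes was -0.02.

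THBD, which encodes thrombomodulin, fell from 63.7 ± 2.3 CPM to 4.01 ± 0.20 CPM (SD, n = 3 per group), a log2 fold change of -3.99 (SE 0.08). TXNIP, which restrains glucose uptake and binds thioredoxin, fell from 144 ± 0.89 to 40.1 ± 2.0 CPM. The immediate early transcription factor EGR1 fell by 2.07 on the log2 scale, with log2 fold changes of -2.31 for BEX4, -1.93 for BEX2 and -1.95 for SLFN5. AC016831.6 fell by 2.07 and the antisense transcript MRPL23-AS1 by 1.86; reads of an antisense gene cannot be separated from its partner without a strand setting. Among higher genes, AGR2, a protein disulfide isomerase of secretory epithelia, rose from 52.6 ± 4.9 to 162 ± 3.3 CPM (log2 fold change 1.63, SE 0.07). BCAS1 rose by 2.55 on the log2 scale, ZNF696 by 1.97, the protocadherins PCDH18 and PCDH7 by 1.77 and 1.64, GUCD1 by 1.64 and the long non-coding RNA LINC00261 by 1.62. TGIF2, a homeobox repressor that also forms part of the read-through gene TGIF2-RAB5IF, rose by 1.76. The sum over that locus rose by 0.65, but it includes RAB5IF, whose own log2 fold change was 0.24. UTP14C, a retrocopy whose reads can be shared with UTP14A, was higher by 1.74, but its adjusted p of 0.0481 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment rose to 0.155 without control replicate 1, 0.147 without control replicate 2, 0.121 without control replicate 3, and 0.118 without SIRT4 replicate 1 or 2.

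A further 3 of the largest changes lie at read-through loci, where a gene shares exons with its neighbours. BLOC1S5-TXNDC5 was listed at 0 in all 3 control libraries and at 203 ± 44.0 CPM in SIRT4 libraries (SD, n = 3), while TXNDC5 fell from 271 ± 6.2 to 73.8 ± 10.7 CPM. The sum over BLOC1S5-TXNDC5, TXNDC5 and BLOC1S5 was 297.7 ± 3.5 CPM in control and 294 ± 31.0 CPM in SIRT4 libraries (exact two-sided permutation p = 1). P2RX5-TAX1BP3 fell by 2.53 on the log2 scale, while the sum over its locus was 0.16 higher and neither component gene passed.

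**Figure D2:**
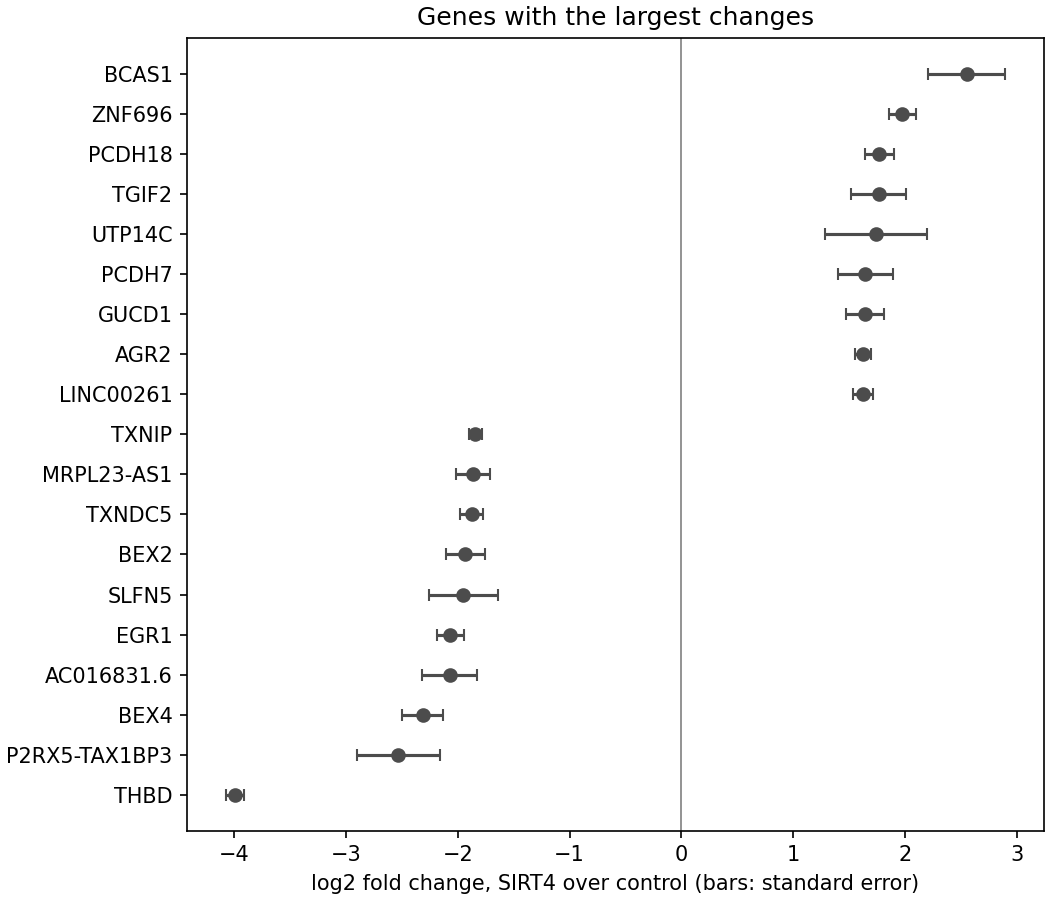
Log2 fold change of SIRT4 over control for the genes with the largest changes past the threshold, higher and lower, with the standard error as bars; BLOC1S5-TXNDC5, listed at 0 in control, is not drawn. THBD lies farthest to the left at -3.99 and BCAS1 farthest to the right at 2.55.

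Genes of DNA replication rose together. Of 37 tested members of the DNA replication and S phase list, 32 were higher and 1 was lower, and adjusted over the list alone 33 were higher and 1 lower. MCM2 and MCM6, subunits of the replicative helicase, rose by 0.99 and 1.07 on the log2 scale, and the S-phase transcription factor E2F1 rose by 0.87. RRM2, the lower member and named after its value was seen, fell by 0.60. The median log2 fold change of the list was 0.67 (camera adjusted p = 4.6e-28, and adjusted p = 0.0221 with an estimated correlation). Of 18 tested replication-dependent histone genes, 4 were higher and none lower, and adjusted over the list alone 4 were higher (camera adjusted p = 0.000597; adjusted p = 0.102 with an estimated correlation). H2BC4 and H3C2 rose by 1.08 and 2.31, but these near-identical genes are measured with uncertainty. The mitosis and G2/M list had 11 higher and 2 lower of 35 (16 and 3 adjusted over the list alone). Only 6 were higher without control replicate 1, control replicate 3 or SIRT4 replicate 2, and 7 without SIRT4 replicate 3. The list included the kinase and cyclin genes AURKA and CCNB1, higher by 0.44 and 0.50, and the phosphatase gene CDC25B, lower by 0.60 on the log2 scale (camera adjusted p = 0.00439; adjusted p = 0.148 with an estimated correlation).

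Lipid synthesis genes were also higher. Of 23 tested cholesterol synthesis genes, 13 rose and none fell, or 17 and 1 adjusted over the list alone. LSS, FDPS and MVD, enzymes of the sterol and mevalonate pathway, rose by 0.85, 0.76 and 0.74 on the log2 scale, and the list median was 0.47 (camera adjusted p = 2.09e-12, and adjusted p = 0.0455 with an estimated correlation). Of 15 fatty acid synthesis genes, 8 rose and none fell, or 10 and none adjusted over the list alone. Fatty acid synthase, FASN, rose from 2226 ± 117 to 4339 ± 42.5 CPM (SD, n = 3 per group), the citrate lyase ACLY rose by 0.94 on the log2 scale, and the desaturase FADS2 by 1.22. That list's camera adjusted p was 3.59e-09, with adjusted p = 0.0723 with an estimated correlation.

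Glycolytic genes followed the same direction, with 12 of 22 higher and 1 lower, or 13 and 3 adjusted over the list alone, and 2 lower without SIRT4 replicate 2. TPI1, PKM and PGK1 rose by 0.93, 0.85 and 0.65 on the log2 scale, whereas the hexokinase HK2, named after its value was seen, fell by 0.80. The list median was 0.35 (camera adjusted p = 8.53e-08, and adjusted p = 0.0455 with an estimated correlation). In the TCA cycle and pyruvate dehydrogenase list 11 of 31 were higher and none lower (17 and 1 adjusted over the list alone), or 7 higher without control replicate 3, among them PDHB (0.63) and IDH3B (0.61). The list's camera adjusted p was 4.34e-06, with adjusted p = 0.0831 with an estimated correlation. In the nuclear-encoded respiratory chain 17 of 42 were higher and 1 lower (22 and 1 adjusted over the list alone; none lower without control replicate 1, control replicate 3, SIRT4 replicate 2 or SIRT4 replicate 3), among them NDUFB10 (0.58), ATP5MC3 (0.51) and NDUFS1 (0.38), with a camera adjusted p of 4.57e-06 and adjusted p = 0.0669 with an estimated correlation. Of 13 mitochondrially encoded genes 6 were higher (8 adjusted over the list alone), with MT-CYB, MT-ND1 and MT-ND2 up by 0.39, 0.39 and 0.49 (camera adjusted p = 0.000229; adjusted p = 0.343 with an estimated correlation).

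The targets of ATF4, the transcription factor of the amino acid response, fell. Of 30 members 19 were lower and none higher, or 20 and none adjusted over the list alone. The pseudokinase gene TRIB3 fell by 1.23 on the log2 scale, DDIT4, an inhibitor of mTORC1 that is also in the hypoxia list, by 0.89, and asparagine synthetase, ASNS, by 0.82. The median was -0.44 (camera adjusted p = 2.4e-14; adjusted p = 0.0694 with an estimated correlation). The immediate early and MAPK output list had 13 lower and 1 higher of 26, or 16 and 1 adjusted over the list alone. JUN fell from 492 ± 4.0 to 148 ± 6.0 CPM (SD, n = 3 per group), the ERK phosphatase DUSP5 fell by 1.73 on the log2 scale and the receptor EPHA2 by 0.69; IER2, named after its value was seen, rose by 0.91. That list's median was -0.48 (camera adjusted p = 5.66e-09; adjusted p = 0.0669 with an estimated correlation).

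**Figure D3:**
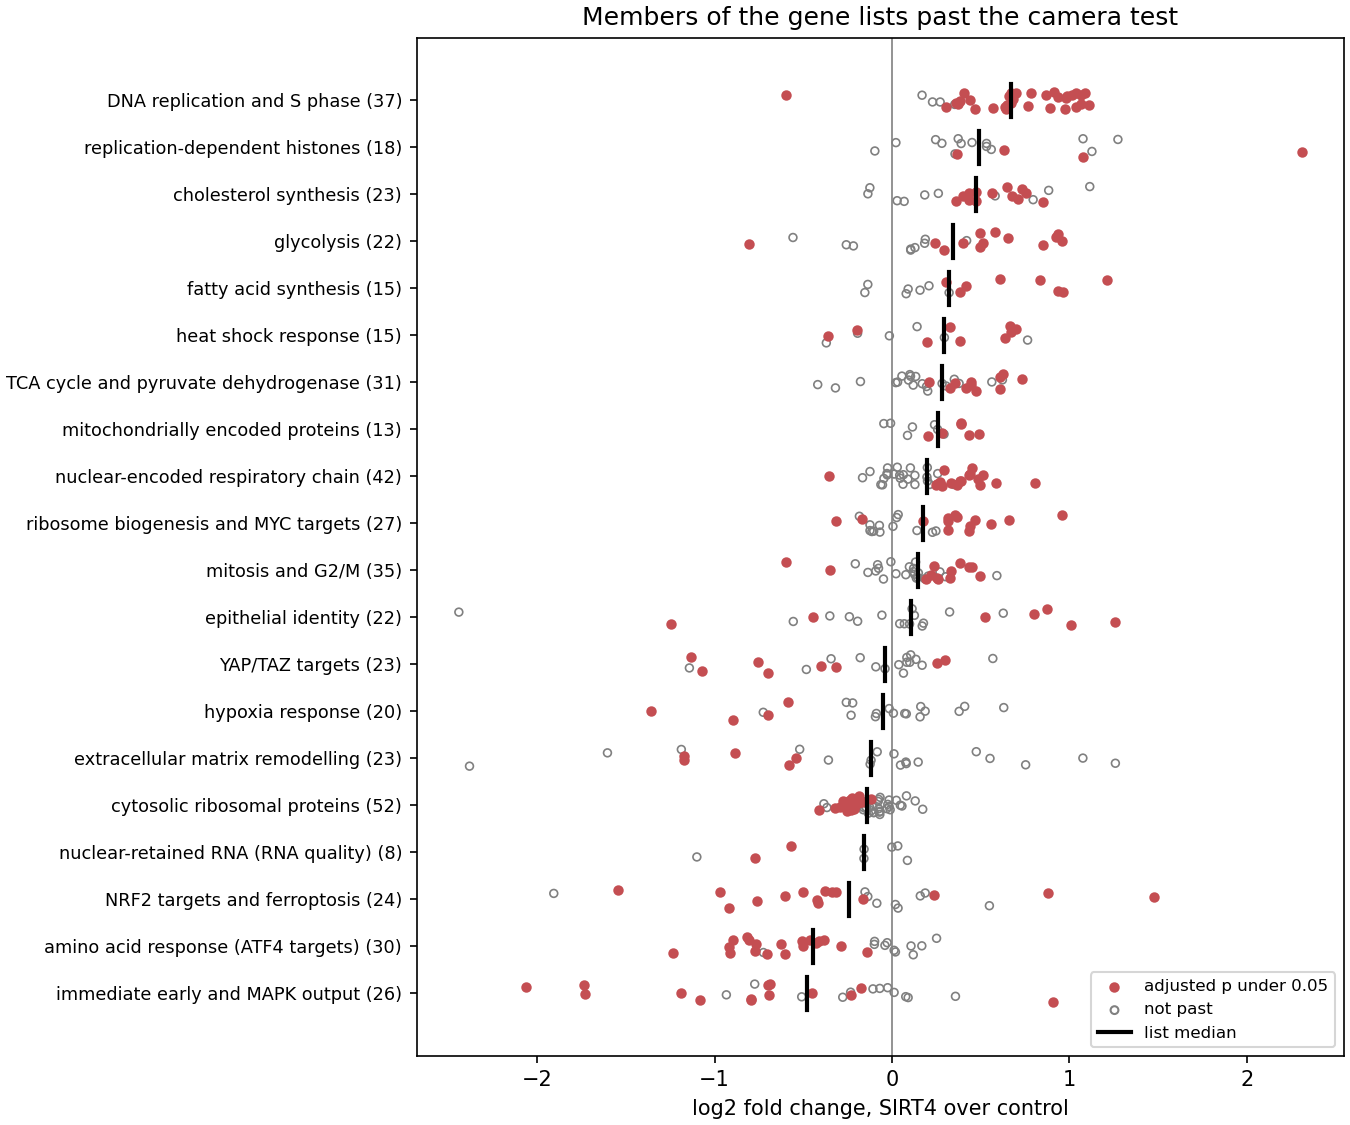
Log2 fold change of SIRT4 over control for each tested member (points) of the 20 gene lists past the camera test, with the number of tested members in brackets and the list median as a black bar. Filled points have an adjusted p under 0.05; the DNA replication list lies highest with a median of 0.67 and the immediate early list lowest at -0.48.

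The NRF2 and ferroptosis list had 12 lower and 3 higher of 24 (12 and 4 adjusted over the list alone). Heme oxygenase, HMOX1, fell by 0.97 on the log2 scale, while the transferrin receptor TFRC rose by 1.48 and PGD, of the pentose phosphate pathway, by 0.88 (camera adjusted p = 0.00116; adjusted p = 0.0909 with an estimated correlation). In the extracellular matrix remodelling list 5 of 23 were lower and none higher (5 and none adjusted over the list alone). The urokinase gene PLAU fell by 1.18 on the log2 scale and the integrin gene ITGA3 by 0.58 (camera adjusted p = 0.0073; adjusted p = 0.102 with an estimated correlation). Of 23 YAP/TAZ targets 6 were lower and 2 higher (6 and 3 adjusted over the list alone; 1 higher without control replicate 1, control replicate 3, SIRT4 replicate 2 or SIRT4 replicate 3), with CCN1, CCN2 and AXL down by 1.13, 0.70 and 0.75; the camera adjusted p was 0.0235, with adjusted p = 0.204 with an estimated correlation and 0.0708 without control replicate 2. Of 20 hypoxia genes 4 were lower, the same number adjusted over the list alone, including VEGFA (-1.36) and BNIP3L (-0.59), although the median was -0.05. The camera adjusted p of 0.0342 became an adjusted p = 0.324 with an estimated correlation, 0.156 without control replicate 2 and 0.0639 without SIRT4 replicate 1.

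Of 22 epithelial genes 5 were higher and 2 lower (6 and 4 adjusted over the list alone), with 1 lower without control replicate 1, control replicate 3, SIRT4 replicate 1 or SIRT4 replicate 2. The simple-epithelium keratins KRT8, KRT18 and KRT19 rose by 1.26, 1.01 and 0.88 on the log2 scale; keratins have many processed pseudogenes, so their reads can be shared. The camera adjusted p was 0.0235, with adjusted p = 0.215 with an estimated correlation and 0.1001 without control replicate 2. The heat shock list had 7 higher and 2 lower of 15 (9 and 3 adjusted over the list alone), but none was lower without control replicate 1, control replicate 3, SIRT4 replicate 1 or SIRT4 replicate 2, and 1 without SIRT4 replicate 3. It held the chaperone genes DNAJA1, HSP90AA1 and HSPA8, up by 0.67, 0.64 and 0.67 (camera adjusted p = 0.000468; adjusted p = 0.102 with an estimated correlation). In the ribosome biogenesis and MYC list 12 of 27 were higher and 2 lower (14 and 4 adjusted over the list alone; 1 lower whichever of the 6 libraries was left out), with NCL up by 0.43 and TFDP1 by 0.66 (camera adjusted p = 0.000915; adjusted p = 0.0723 with an estimated correlation). Cytosolic ribosomal protein genes fell slightly, 18 of 52 lower and none higher (24 and 1 adjusted over the list alone), with RPL28 and RPL10A down by 0.41 and 0.29 (camera adjusted p = 0.000117; adjusted p = 0.102 with an estimated correlation). These genes also have many pseudogene copies.

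Of 8 nuclear-retained RNAs, a list fixed as a sign of RNA quality, 2 were lower and none higher (3 adjusted over the list alone). MEG3 fell by 0.77 and OIP5-AS1 by 0.57 on the log2 scale. The camera adjusted p was 0.0235, with adjusted p = 0.169 with an estimated correlation, 0.0682 without control replicate 2 and 0.0529 without SIRT4 replicate 3. The share of counts from lncRNA genes was 1.505% ± 0.06 in control and 1.33% ± 0.04 in SIRT4 libraries (SD, n = 3 per group), lower in all 3 (exact two-sided permutation p = 0.1, the smallest possible). The nuclear RNAs MALAT1 (248 ± 76.5 and 223 ± 27.5 CPM; exact two-sided permutation p = 0.8) and NEAT1 (617 ± 277 and 288 ± 136 CPM; exact two-sided permutation p = 0.2) varied within groups (SD, n = 3 per group). No measure of RNA quality was analysed here. The share of counts from mitochondrial genes was 5.70% ± 0.09 against 5.76% ± 0.38 (exact two-sided permutation p = 0.8).

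Several lists did not pass although single members did. The unfolded protein response list had 5 higher and 5 lower of 22 (7 and 6 adjusted over the list alone; 3 higher without SIRT4 replicate 1): the endoplasmic reticulum chaperone HSPA5 and the sensor ERN1 fell by 0.88 and 1.17 on the log2 scale, and CALR rose by 0.67 (camera adjusted p = 0.698). Of 24 genes of glutamine and glutamate metabolism 4 were higher and 5 lower, the same numbers adjusted over the list alone, with GOT1 down by 0.66 and SLC38A1 up by 0.43 (camera adjusted p = 0.186). The p53 list had a camera adjusted p of 0.062, with GADD45A down by 1.07. Mitochondrial stress genes were mixed, with GDF15 down by 0.92 and HSPE1 up by 0.60 (camera adjusted p = 0.294). Fatty acid oxidation (camera adjusted p = 0.104), autophagy and lysosome (0.281), interferon-stimulated genes (0.741), NF-kappaB (0.201), Wnt (0.225), the sirtuin family (0.26), mesenchymal genes (0.401) and the classical (0.0567) and basal-like (0.201) pancreatic cancer programmes did not pass. Within these lists the autophagy receptor SQSTM1 fell by 0.54 on the log2 scale and the cytokine LIF by 0.77, while the carnitine palmitoyltransferase CPT1A rose by 0.53 and the EGF receptor ligand AREG fell by 1.36. TGF-beta targets did not pass either (camera adjusted p = 0.947), and their median of 0.04 was opposite in sign to the direction of the fry test.

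Few markers of other cell types changed. No fibroblast marker changed among 7 tested (list camera adjusted p = 0.741), which does not mean that all were absent. Mean levels were 172 CPM for COL1A1, 152 for FBLN1, 46.3 for COL6A3, 11.1 for THY1 and 6.18 for COL3A1. PDGFRB (2.51), ACTA2 (2.31), PDGFRA (0.066) and LUM (0.0129) were lower, and COL1A2, DCN and FAP were listed at 0. Of 6 leukocyte markers only CD68, a lysosomal gene, was lower (-0.90), and its adjusted p of 0.0178 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment became 0.0558 without control replicate 1 and 0.052 without SIRT4 replicate 2 (list camera adjusted p = 0.607). The HEK293T-type list had 1 member higher of 7, PAX2 (0.51, list camera adjusted p = 0.19), but 2 higher of 8 tested without control replicate 1 or control replicate 2. Of the endothelial and the acinar and endocrine lists, 4 and 1 members passed the low-count filter, too few to test as a list. The synaptophysin gene SYP was lower (-0.44), with an adjusted p of 0.0311 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. However, that adjusted p became 0.0703, 0.0975 and 0.0572 without control replicate 1, 2 and 3, and 0.0953 and 0.101 without SIRT4 replicate 1 and 3.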

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

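The alternatives of division by 4, read-through loci left out, and GC and length offsets were chosen after seeing the data. SIRT4 passed the threshold only under the DESeq2 Wald test (log2 fold change 0.643, adjusted p = 0.0385), and the cause was not tested. That test called more genes in general, 4509 of the same 20786 against 3545 in the main test. Under glmTreat, which asks for a change beyond 1.2-fold and is therefore stricter by construction, 605 genes were higher, 521 lower and 254 changed at least 2-fold. Leaving out 1 library, which leaves fewer samples, gave 1312 to 1570 higher, 978 to 1204 lower and 298 to 394 genes changed at least 2-fold, 16 to 21 lists called, and a SIRT4 log2 fold change of 0.55 to 0.77. With an estimated correlation 3 fixed lists were called in place of 20; fry, which tests lists against no change and not against other genes, called 30. Of 2243 recalculated values of named genes, 63 lost the threshold, 1 gained it and 0 reversed. Replicate numbers did not pair the libraries (deviation correlations of same-numbered libraries 0.01, 0.003 and -0.018); with the replicate block 1450 genes were higher, 1140 lower, 275 changed at least 2-fold and 18 lists were called, with the calls of the hypoxia (adjusted p = 0.0641) and YAP/TAZ (adjusted p = 0.0579) lists lost. Library size only gave 47.1% of calls as higher against 55.0%. Division by 4 left 16440 genes to test in place of 20786, and gave 1980 higher and 1813 lower.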

Other observations

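The tests on snoRNA host genes, label swap and exchange, construct sequence, culture, GC content and length, read-through loci and chromosome 19 were chosen after the result was seen. The proteasome, tubulin and CCT, mitochondrial ribosomal, zinc finger and aminoacyl-tRNA synthetase families were not among the fixed lists. They were added after the main comparison, with their predictions written before their own tests. The snoRNA host genes were lower as a family: of 26 tested SNHG genes and GAS5, 9 were lower and none higher (median log2 fold change -0.35, camera adjusted p = 3.5e-07 over 6 families, and adjusted p = 0.0152 with an estimated correlation). GAS5, which carries a 5' terminal oligopyrimidine tract like ribosomal protein mRNAs, fell from 180 to 82.5 CPM, and SNHG32, SNHG29 and SNHG5 fell by 0.88, 0.70 and 0.69 on the log2 scale. The fixed list of nuclear-retained RNAs was lower too (camera adjusted p = 0.0235, and adjusted p = 0.169 with an estimated correlation). Its camera adjusted p was 0.0682 without control replicate 2 and 0.0529 without SIRT4 replicate 3. The lncRNA share was also lower (1.505% in control, 1.33% in SIRT4 libraries). NEAT1 (617 and 288 CPM, exact two-sided permutation p = 0.2) and MALAT1 (248 and 223 CPM, exact two-sided permutation p = 0.8) overlapped between the groups. These measures share transcripts and are not independent signs. SNHG14 belongs to both the list and the SNHG family, and NEAT1 and MALAT1 are on the list. MEG3 and OIP5-AS1 are on the list and count in the lncRNA share. No measure of RNA quality was analysed here. Proteasome subunits rose, 20 higher and 1 lower of 37 (median 0.30, camera adjusted p = 3.22e-11; adjusted p = 0.00778 with an estimated correlation), with PSMD4 and PSMD2 up by 0.71 and 0.81. Tubulins and the CCT chaperonin, which folds tubulin, rose in 12 and fell in 1 of 23 (camera adjusted p = 3.1e-06; adjusted p = 0.0637 with an estimated correlation), with TUBA1B and CCT5 up by 0.68 and 0.61; an antisense gene was taken out of this family after a first run, which left the outcome unchanged. Mitochondrial ribosomal proteins had 14 higher and 3 lower of 78 (camera adjusted p = 0.00209; adjusted p = 0.0713 with an estimated correlation). Zinc finger genes, 21 higher and 38 lower of 482, and cytosolic aminoacyl-tRNA synthetases, 5 higher and 4 lower of 20, did not move together (camera adjusted p = 0.579 and 0.72); SARS1 and AARS1, both ATF4 targets, fell by 0.70 and 0.51 while KARS1 rose by 0.45.

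SIRT4 was only 1.55-fold higher in libraries labelled as overexpressing it and did not pass the threshold, while 3545 genes changed. Its values alone do not establish that SIRT4 RNA was overexpressed. The count of genes within 100000 bases that rose was 0, and PXN there fell by 0.14. This count cannot decide whether transgene reads were given to a neighbouring gene. Genes that do not overlap SIRT4 would not be expected to take its reads. The overlapping gene RNU6-1088P, at 0 CPM in both groups, was not tested. A swap of single libraries between the groups is argued against by the count of libraries out of place on principal component 1 or in SIRT4 CPM, also 0. An exchange of all labels of the 2 groups stays open, since it leaves component 1 as it is and SIRT4 did not pass (adjusted p = 0.0752 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A construct with recoded or foreign sequence may not map to the SIRT4 gene, and the log2 fold change of 0.633 cannot exclude it, because reads that map to no annotated gene are not in the table.

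The S phase, cholesterol, fatty acid and glycolysis lists rose, and the ATF4 and immediate early lists fell, although the fatty acid (adjusted p = 0.0723 with an estimated correlation), ATF4 (adjusted p = 0.0694 with an estimated correlation) and immediate early (adjusted p = 0.0669 with an estimated correlation) lists did not pass that stricter test. A trend with GC content and transcript length is argued against: with both removed and the preset correlation, 0 of the 6 lists lost their call or fell to 0.5 of their median, and the S phase median was 0.67 before and after. A single aberrant library is argued against as well, since the number of the 6 lists whose median fell under 0.5 of its value without 1 library was 0. SIRT4 overexpression is the biological difference that the design names, and it cannot be told apart from a difference in density, medium or passage between the cultures, which may also lower immediate early genes (median -0.479), because the labels give no culture record. With 10 splits of the 6 libraries the share is never under 0.1. The real split, the 1 split of the 10 to reach its count, called 3545 genes and the highest other split 6. Every other split mixes the groups, so a group difference of any cause raises the spread within its sides and lowers its count.

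The 5 called read-through genes had a median absolute log2 fold change of 2.49, against 0.227 for the sums over their loci, but these sums include other genes and at PDXDC2P-NPIPB14P the sum (-0.50) moved about as much as the gene (-0.57), so whether counting moved reads between such genes and their components stays open.

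A region of chromosome 19 was highly expressed in all 6 libraries. Between ACTN4 and AKT2 (GRCh38 chromosome 19, 38647649 to 40285536) 46 tested protein-coding genes had a median of 179 CPM, against 33.8 CPM in the 20 genes before and 24 CPM in the 20 genes after, with SUPT5H at 2246, PSMC4 at 1606 and AKT2 at 2169 CPM and C19orf47, next beyond AKT2, at 24.4 CPM. The highest window of 20 genes there had a median of 313 CPM, above the 156 CPM of the highest window on any other chromosome; chance clustering is argued against by a permutation test with 1000 permuted gene orders (p = 0.001, the smallest they can give), and SIRT4 overexpression by the region's median log2 fold change of -0.057. A gain of this region is a candidate explanation: AKT2 amplification is known in some pancreatic cancer lines, PANC-1 among them, and CDKN2A and CDKN2B, often deleted in such lines, were listed at 0 in all 6 libraries. Libraries from a cell line other than CAPAN-2 cannot be excluded: only 2 of 25 matched genes of the classical programme reached 5 CPM (AGR2 and CDH17). Epithelial genes were mixed. In CPM, the highest were KRT8 1460, KRT19 968, KRT18 591, JUP 374, TJP1 124, CDH1 112, CLDN4 112 and DSP 102. CLDN7 92.7, ELF3 76.2, OCLN 59.2, EPCAM 40.4, ESRP2 35.9, CLDN3 22, ESRP1 21.4 and KRT7 8.01 followed. The lowest were ST14 4.79, MAL2 2.08, CRB3 1.15, OVOL2 0.995, OVOL1 0.477, PRSS8 0.269, RAB25 0.0762 and GRHL2 0.049. Mesenchymal genes were mixed as well (VIM 3420, ITGA5 254, COL1A1 172, MMP2 92.4, FN1 11.2 and SNAI2 0.036 CPM, TWIST1 listed at 0). The HEK293T-type list was mixed too (HOXB9 124, PEG10 72.6, PAX2 52.2, LIN28B 15.3, GATA3 15.3, CDX2 3.02, HOXA9 0.238, NEFM 0.0871 and NEFL 0.0129 CPM, TLX3 listed at 0). No genotype or reference profile of the line was analysed here.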
